A study of Mus musculus with 4 samples.

How the data were processed

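RNA was sequenced from lineage-negative bone marrow cells of mice, the fraction left after mature blood cells are removed and therefore rich in haematopoietic stem and progenitor cells (HSPC). The cells were taken 6 weeks after polyinosinic-polycytidylic acid (pIpC), an inducer of interferon that is used to switch on interferon-responsive transgenes. Per the labels' protocols, RNA was isolated with a PicoPure kit, and stranded, poly(A)-selected libraries were read as 75-base pairs on a HiSeq2000. The labels also describe a culture medium, without saying whether these cells were cultured before RNA was taken. The series has 4 samples. Their labels give no genotype, so all 4 were left unassigned and no comparison between samples was made.

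The one file used was the authors' deposited table of a comparison between 2 arms. Its name pairs the abbreviations het and WT, and neither the labels nor the column headers state which arm is the numerator or which gene the abbreviation refers to. Per the submitters' processing notes, TopHat2 2.0.13 and DESeq2 1.6.3 were used with the mouse build GRCm38. The read counter, the gene annotation and the strand setting of the counting are not given in the sources used here. Per the file headers, the authors deposited for each gene a signal, the mean normalized count over all libraries. They also deposited a log2 fold change and its standard error, both on the log2 scale. The deposited Wald score is the statistic behind each p-value, and the table also holds the authors' adjusted p-value. The table holds 39017 genes, of which 14592 had no read in any library and no test, which leaves 24425 tested genes. Fold changes are given here as the table has them. The arm in which genes with a positive fold change were more abundant is called the positive arm.

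The deposited values were checked against one another. The deposited Wald score equalled the fold change over its standard error within 4.68e-07. The authors' adjusted p equalled a Benjamini-Hochberg adjustment over all 24425 genes within 3.96e-06, so no gene had been taken out by a filter on abundance. The 1741 genes with a mean under 0.3 fell on 4 exact values, those that a single read in 1 of 4 libraries gives. From these steps the size factors of the 4 libraries were 0.935, 0.999, 1.03 and 1.05, and the signs of the fold changes put 2 libraries in each arm. The steps do not show which sample each library was. A gene with a single read had a log2 fold change no larger in size than 0.0078, so the authors' deposited fold changes were shrunken towards 0 and understate the change, most for genes of low abundance. The mean normalized counts summed to 53421577 over the genes, and the 10 most abundant genes held 4.69% of that sum. Counts per library were not used here, so the only spread given is the authors' standard error, which their model estimates from 2 libraries per arm. It belongs to the shrunken fold change and is small where reads are few. For Hoxa13, with a mean of 0.268, it was 0.014, and for Hoxa10, with a mean of 1084, 0.119. A small standard error at low abundance therefore does not mark a precise fold change. Nothing in the labels says whether the libraries came from separate animals, and the p-values then measure the spread between these libraries.

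Genes with the authors' DESeq2 adjusted p under 0.05 are called changed. Before the data were examined, 31 gene lists were written for cell types of the marrow, pathways and complexes, together with the tests, the rule for named genes and the first set of alternatives. For each list the members past the threshold were counted with the authors' adjusted p and with Benjamini-Hochberg adjustment over the list alone. The median log2 fold change of each list was set against 10000 random lists of the same size, matched on mean abundance in 20 bins. The two-sided permutation p of this test cannot fall below 0.0002, which became an adjusted p of 0.000689. Lists at that value cannot be ranked by it. The deposited Wald scores were tested with cameraPR of limma 3.58.1, a competitive set test, at a preset correlation between genes of 0.01. Over-representation among called genes was tested with Fisher's exact test, two-sided, per direction. Each family of list tests was adjusted by Benjamini-Hochberg. Genes are not independent of one another, and without values per library the correlation between genes could not be estimated, so a preset of 0.05 was run beside 0.01.

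The genes named in the text follow a fixed rule. Npm1 comes first. Then come the 12 largest positive and the 12 largest negative fold changes among called genes with a mean of at least 50. Predicted genes, pseudogenes and receptor segments were passed over in that step. For each list up to 4 called members with the smallest adjusted p are named, 2 per direction, or the 2 with the smallest p where none was called. Genes named outside this rule were chosen after their values were seen, as stated where they appear. A few genes that the rule or the lists take in are counted and not reported here by name.

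The list tests were first tested on simulated data. In 10 tables per size, the authors' rows were shuffled between genes of like abundance and whole lists, of 200 genes at most in all, were shifted by 1 or 2 standard errors. For the 24425 genes of this comparison, the random lists recovered 66.1% of the lists shifted by 1 standard error and cameraPR also 66.1%. Fisher's exact test recovered 28.6% of them. With a shift of 2 standard errors these shares were 100%, 98.1% and 77.4%. Of the lists left unshifted beside the larger shift, 0.948%, 3.32% and 9.00% were called, the last by Fisher's exact test. The shuffling removes correlation between genes, which these shares therefore leave out.

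Coordinates, gene types and transcripts came from GENCODE M21, on the same build, in which 97.9% of the tested genes had a place. Transcripts were aligned with blastn 2.17.0 and, base by base, with Biopython 1.88. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3. The alternatives tried were other thresholds, a minimum fold change, a minimum mean of 10, other gene universes, unmatched random lists, other rankings and presets in the set test. Centring on genes with a mean of at least 50, removal of a trend on GC content and transcript length, and lists without members shared with another list were added after the data were seen.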

Results

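Transcriptomes of lineage-negative marrow cells, 6 weeks after pIpC, were available as a single comparison made by the authors, with 4 libraries behind it and 2 in each arm. The title of the series concerns ribosome biogenesis factors in acute myeloid leukaemia with mutant NPM1, the gene of a nucleolar phosphoprotein. The comparison asks how gene expression in these progenitors differs between the arms. Because the sources used here do not state which arm is the numerator, directions are given for the positive arm, in which genes with a positive fold change were more abundant.

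The largest change lay in the Hoxa cluster, genes of homeodomain transcription factors that act in stem and progenitor cells and are highly expressed in leukaemia with mutant NPM1. Genes of megakaryocytes and platelets, of granulocyte-monocyte progenitors and of the p53 response were also higher in the positive arm, while erythroid genes and genes of DNA replication and mitosis were lower. Of 24425 tested genes in the authors' deposited table, 919 passed a DESeq2 adjusted p of 0.05, 477 of them positive and 442 negative. Most changes were small. The median size of the log2 fold change among the called genes of the authors' deposited table was 0.36. In all 28 genes had an adjusted p under 0.05 and a log2 fold change of at least 1 in size, 19 positive and 9 negative. The 19 include pseudogene copies of Rpl30, with log2 fold changes from 1.12 to 2.41, which may not measure expression, as set out below. At an adjusted p of 0.01 the authors' deposited table held 557 genes.

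Npm1 (chromosome 11, 33152287 to 33163206, GRCm38) had a mean normalized count of 82038 and a log2 fold change of -0.06 (SE 0.05) in the authors' deposited table, with a DESeq2 adjusted p of 0.888. No difference in its total level was detected. Counts per gene do not tell a mutant from a wild-type allele.

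**Figure D1:**
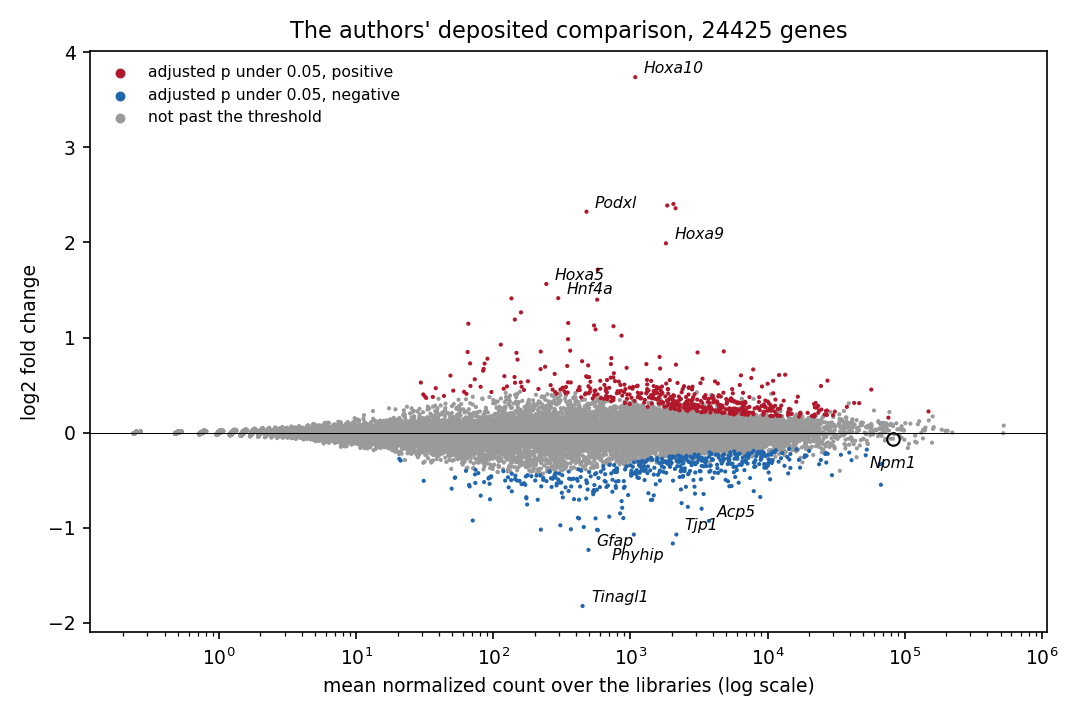
Each point is 1 of the 24425 tested genes of the authors' deposited table, with the mean normalized count over the libraries on a log axis and the log2 fold change on the vertical axis, coloured by whether the adjusted p was under 0.05. Hoxa10 stands highest at 3.74 and Tinagl1 lowest at -1.82, and Npm1 (open circle) lies at -0.06.

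Of the 11 measured Hoxa genes, 8 were called in the authors' deposited table, all positive, and the count adjusted over the list alone was also 8. Hoxa10 (chromosome 6, 52231197 to 52240854) had the largest fold change of all tested genes in the authors' deposited table, 13.3-fold (log2 3.74, SE 0.12, DESeq2 adjusted p = 7.75e-211). Hoxa9 (52223100 to 52231089) was 3.97-fold higher there, with a log2 fold change of 1.99 (SE 0.08) and a DESeq2 adjusted p of 1.37e-118 in the authors' deposited table. Hoxa5, Hoxa7, Hoxa6 and Hoxa3 followed at log2 fold changes of 1.56, 1.40, 1.19 and 0.93 in the authors' deposited table, and Hoxa4 and Hoxa2 at 0.48 and 0.47. The authors' deposited table gives Hoxa11 and Hoxa13, at one end of the cluster, means of 0.785 and 0.268 normalized counts, too few for a change to be detected. Hoxa3, outside the fixed rule like Hoxa4, Hoxa2, Hoxa11 and Hoxa13, overlaps Hoxa4, Hoxa5 and Hoxa6 in the annotation, so part of the reads of these 4 genes may not be separable. The list median of 0.93 lay above all 10000 matched random lists (adjusted p = 0.000689). The set test gave an adjusted p of 7.61e-98 with cameraPR, and 3.15e-06 in its rank-based form. Both presume nearly independent genes, although reads of 4 members may not be separable.

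**Figure D2:**
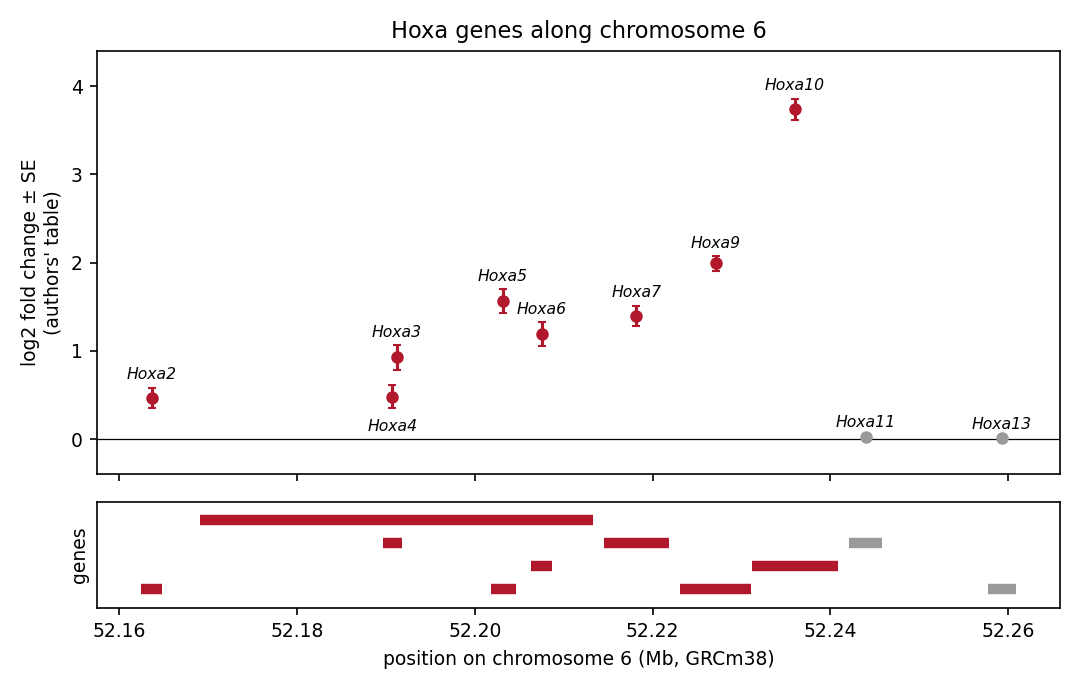
The upper panel shows the log2 fold change of the Hoxa genes named in the text in the authors' deposited table, with bars of 1 standard error, at the middle of the gene on chromosome 6 (Mb, GRCm38). The lower panel draws the gene bodies, and red marks genes with an adjusted p under 0.05, which run from Hoxa2 to Hoxa10.

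The Hoxb genes did not pass the threshold. None of the 9 measured members was called in the authors' deposited table by DESeq2, 1 was past an unadjusted p of 0.05, and that gene, Hoxb5, was the 1 called when adjusted over the list alone (log2 0.26, SE 0.09, adjusted p = 0.0956 over all genes). The authors' deposited table gave Hoxb3 a log2 fold change of 0.12 (SE 0.10). All 9 had a positive fold change, and the Hoxb median of 0.03 lay above the random lists (adjusted p = 0.00395). The set test did not call the list (cameraPR adjusted p = 0.137), though its rank-based form did (adjusted p = 0.0197). Of the Hoxb members, 6 had means under 10. Among members with a mean of at least 10 the random-list adjusted p was 0.0745. Among 9 cofactors of the Meis and Pbx families, which bind DNA together with Hox proteins, 3 were called in the authors' deposited table, also when adjusted over the list alone. Meis1 was higher at log2 0.49 (SE 0.10) in the authors' deposited table, with a DESeq2 adjusted p of 0.000115. Pbx3 was lower at -0.43 (SE 0.12, DESeq2 adjusted p = 0.0129 in the authors' deposited table). The list as a whole was not called (cameraPR adjusted p = 0.279, random lists 0.988).

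The genes given next follow the naming rule, which passes over predicted genes, pseudogenes and receptor segments. Beyond the Hoxa genes, the largest positive log2 fold change among them in the authors' deposited table was that of Podxl, a sialomucin of the CD34 family, at 2.32 (SE 0.13). Hnf4a, a nuclear receptor best known from liver, followed at 1.41 (SE 0.13). Mgat4c and Cyp2b10, a glycosyltransferase and a cytochrome P450, stood at 1.41 (SE 0.14) and 1.26 (SE 0.14) in the authors' deposited table. Hopx, a small homeodomain protein, Phlda3, a target of p53, and Cd177, a neutrophil surface glycoprotein, followed at 1.15, 1.13 and 1.09 in the authors' deposited table. The largest negative change was that of Tinagl1, an extracellular matrix protein, 3.54-fold lower in the authors' deposited table (log2 -1.82, SE 0.13, DESeq2 adjusted p = 5.58e-43). Gfap, an intermediate filament of astrocytes, and Phyhip were lower at -1.23 and -1.17 in the authors' deposited table, as were Tjp1, the tight junction scaffold ZO-1, at -1.07 and Fahd1 at -1.07. Lrig1, a negative regulator of receptor tyrosine kinases, and the histone gene Hist2h2be stood at -1.03 and -1.02 in the authors' deposited table, and Rgs9bp, Acp5, the tartrate-resistant acid phosphatase, and Kif21a at -0.97, -0.93 and -0.92. The authors' deposited table placed Cacna1g, a T-type calcium channel, and Ephx2, an epoxide hydrolase, both at -0.90. The DESeq2 adjusted p of each of these genes in the authors' deposited table was 6.5e-10 or smaller. In the annotation Fahd1 overlaps Hagh, Lrig1 overlaps Slc25a26 and Mir7041, Gfap overlaps Gm26668 and Hopx overlaps Hopxos. Part of their reads may not be separable. Among the positive calls passed over by the naming rule were 6 pseudogene copies of Rpl30, with log2 fold changes from 0.85 to 2.41 in the authors' deposited table, the largest above that of Podxl.

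Megakaryocyte and platelet genes rose as a group. All 36 measured members had a positive fold change in the authors' deposited table, 18 were called and 27 were called when adjusted over the list alone. Their median log2 fold change was 0.36, above all 10000 matched random lists (adjusted p = 0.000689), with a cameraPR adjusted p of 2.84e-33. In the authors' deposited table Serpine2, a protease inhibitor, rose by 0.80 (SE 0.10, DESeq2 adjusted p = 7.05e-12) and Thbs1, the platelet protein thrombospondin 1, by 0.61 (SE 0.09, adjusted p = 1.83e-08). Erythroid genes fell. Of 43 measured members 12 were called in the authors' deposited table, all negative, and 17 when adjusted over the list alone. The median was -0.20 (random lists, adjusted p = 0.000689) and the cameraPR adjusted p 2.36e-16. Kel, a blood group protein of the red cell surface, had a log2 fold change of -0.61 (SE 0.06, DESeq2 adjusted p = 4.07e-22) in the authors' deposited table. Ppox, an enzyme of haem synthesis, had -0.56 (SE 0.06, DESeq2 adjusted p = 1.29e-16 in the authors' deposited table) and overlaps B4galt3 in the annotation.

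Granulocyte-monocyte progenitor and primary granule genes were also higher in the positive arm. All 19 measured members had positive fold changes in the authors' deposited table, 6 were called and 12 when adjusted over the list alone, with a median of 0.17 (random lists, adjusted p = 0.000689; cameraPR, adjusted p = 3.92e-14). Elane, neutrophil elastase, and Srgn, serglycin, stood at 0.31 (SE 0.06) and 0.30 (SE 0.05) in the authors' deposited table, with DESeq2 adjusted p of 2.21e-05 and 1.38e-06. Of 27 monocyte and macrophage genes 8 were called in the authors' deposited table, all positive, and 9 when adjusted over the list alone, among them Ly6c2 at 0.55 (SE 0.08) and F13a1, coagulation factor XIII, at 0.49 (SE 0.08). The monocyte list was called by cameraPR (adjusted p = 1.4e-05), but not by a rank-based form of it (adjusted p = 0.104), and its median of 0.04 did not stand apart from random lists (adjusted p = 0.343). Among 29 mature neutrophil genes 2 were called in the authors' deposited table, Cd177 and Anxa1 (log2 0.25, SE 0.08), and 6 when adjusted over the list alone, with a cameraPR adjusted p of 7.69e-06 and a random-list adjusted p of 0.00465. Among 27 genes of basophils, mast cells and eosinophils 2 were called in the authors' deposited table, Gata2 at 0.31 (SE 0.08) and Hdc, histidine decarboxylase, at 0.27 (SE 0.08), and 3 when adjusted over the list alone. That list's cameraPR adjusted p was 0.0157, and 0.0968 with a preset correlation of 0.05, and its random-list adjusted p was 0.00661. Dendritic cell and MHC class II genes went both ways. H2-DMa and Tcf4 were the 2 called among 27 members, at 0.34 (SE 0.07) and 0.22 (SE 0.07) in the authors' deposited table. Yet the list median was -0.14 (random lists, adjusted p = 0.000689). The list was not called by cameraPR (adjusted p = 0.145), but was called negative with log2 fold changes as its ranking (0.0142) and in its rank-based form (0.0296). Adjusted over the list alone 5 members were called, 2 positive and 3 negative. H2-DMa overlaps Brd2 in the annotation.

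Of 37 haematopoietic stem cell genes 6 were called in the authors' deposited table, all positive, and 10 when adjusted over the list alone, 9 positive and 1 negative. The list median was 0.08 (random lists, adjusted p = 0.00186; cameraPR, adjusted p = 4.88e-08). The called members include Hoxa9 and Meis1, which also stand in the Hoxa and the cofactor lists. Without the members shared with another list 27 genes remained, with a cameraPR adjusted p of 0.0941 and a random-list adjusted p of 0.434. Early lymphoid and multipotent progenitor genes were not called as a list (19 measured, cameraPR adjusted p = 0.848, random lists 0.42), with 2 members called in the authors' deposited table, Cd48 among them at 0.27 (SE 0.08), and 3 members when adjusted over the list alone.

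Few markers of other cells that the marrow fraction could hold were called. Of 33 B lineage genes 1 was called in the authors' deposited table, Cd22 at -0.48 (SE 0.13), and 9 when adjusted over the list alone, 3 positive and 6 negative. The median was -0.07 (random lists, adjusted p = 0.0142; cameraPR, adjusted p = 0.118). Among 19 plasma cell genes Xbp1 was higher at 0.23 (SE 0.06) and Ighg3 lower at -0.39 (SE 0.12) in the authors' deposited table, the same 2 calls as when adjusted over the list alone, and the list was not called (cameraPR adjusted p = 0.757, random lists 0.805). Of 37 T, NK and innate lymphoid genes Il1rl1, the receptor of interleukin 33, was the 1 called in the authors' deposited table and when adjusted over the list alone, at -0.32 (SE 0.07). The median of that list was 0.05, of the other sign (random lists, adjusted p = 0.0281; cameraPR, adjusted p = 0.699), and the random-list adjusted p was 0.0889 without the member shared with another list. Of 29 stromal and endothelial genes, 2 were called in the authors' deposited table and when adjusted over the list alone, Fn1, fibronectin, at 0.61 (SE 0.14) and Ly6c1 at 0.42 (SE 0.12), and the list was not called (cameraPR adjusted p = 0.699, random lists 0.795).

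Genes of cell division fell. Of 40 G2/M phase genes 14 were called in the authors' deposited table, all negative, and 25 when adjusted over the list alone, and 1 member had a positive fold change. The median was -0.16 (random lists, adjusted p = 0.000689; cameraPR, adjusted p = 2.86e-22). Cenpf, a kinetochore protein, had a log2 fold change of -0.39 (SE 0.06, DESeq2 adjusted p = 3.08e-08) and Mki67, which encodes the proliferation marker Ki-67, -0.33 (SE 0.06, adjusted p = 4.19e-06) in the authors' deposited table. Of 50 S phase genes 5 were called in the authors' deposited table, all negative, and 6 when adjusted over the list alone, with Lig1, DNA ligase 1, at -0.26 (SE 0.06) and Tyms, thymidylate synthase, at -0.23 (SE 0.06). Their median was -0.09 (random lists, adjusted p = 0.000689; cameraPR, adjusted p = 1.52e-08). Targets of p53 rose. Of 42 members 10 were called in the authors' deposited table, all positive, and 11 when adjusted over the list alone, with a cameraPR adjusted p of 5.76e-09 and a random-list adjusted p of 0.0093 at a median of 0.07. Phlda3 and Ccng1, cyclin G1, stood at 1.13 (SE 0.11) and 0.57 (SE 0.06) in the authors' deposited table. Cdkn1a, which encodes the cell cycle inhibitor p21, and Zmat3, both chosen after their values were seen, were at 0.75 (SE 0.13) and 0.78 (SE 0.12) in the authors' deposited table, with DESeq2 adjusted p of 1.07e-06 and 7.24e-09.

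Ribosome biogenesis factors, the subject named in the title, moved slightly and mostly one way. Of 144 measured factors 123 had a positive fold change in the authors' deposited table, and the list median was 0.09 (random lists, adjusted p = 0.000689; cameraPR, adjusted p = 6.89e-08, and 0.00608 with a preset correlation of 0.05). By single genes 5 were called in the authors' deposited table, also when adjusted over the list alone, 3 positive and 2 negative. Ddx21, a nucleolar RNA helicase, and Nip7 were higher at 0.21 (SE 0.05) and 0.26 (SE 0.07) in the authors' deposited table, with DESeq2 adjusted p of 0.00628 and 0.0163. Nop10, part of the H/ACA ribonucleoproteins that guide pseudouridylation, and Imp3, part of the U3 complex, were lower at -0.40 (SE 0.07) and -0.38 (SE 0.07) in the authors' deposited table, with DESeq2 adjusted p of 9.26e-07 and 3.78e-05. Of 49 proteins of the large ribosomal subunit none was called by DESeq2 in the authors' deposited table or when adjusted over the list alone, and 4 had an unadjusted p under 0.05. Their median was 0.08 (random lists, adjusted p = 0.00661; cameraPR, adjusted p = 0.00576, and 0.0968 with a preset correlation of 0.05). Rpl30, which has near-identical pseudogene copies, and Rpl22l1 had the smallest p, at -0.21 (SE 0.07) and -0.16 (SE 0.06) in the authors' deposited table. All 33 measured proteins of the small subunit had positive fold changes in the authors' deposited table, with a median of 0.08 (random lists, adjusted p = 0.0207; cameraPR, adjusted p = 0.000328). With a trend on GC content and transcript length removed that median was 0.06 (random lists, adjusted p = 0.114). The 1 called member was Rps27l, also a p53 target, at 0.20 (SE 0.06) in the authors' deposited table, and it was not called when adjusted over the list alone. Of 75 nuclear-encoded subunits of oxidative phosphorylation 4 were called in the authors' deposited table and when adjusted over the list alone, all negative, among them Uqcr10 at -0.30 (SE 0.08) and Cox7c at -0.24 (SE 0.06), while the list median was 0.02 and the list was not called (cameraPR adjusted p = 0.699, random lists 0.805). None of the 13 mitochondrial mRNAs was called by DESeq2 in the authors' deposited table or when adjusted over the list alone, and 1 had an unadjusted p under 0.05, mt-Nd6 at 0.10 (SE 0.05). The authors' deposited table gave mt-Nd1 -0.10 (SE 0.05), and the mitochondrial list was not called (cameraPR adjusted p = 0.704, random lists 0.645).

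**Figure D3:**
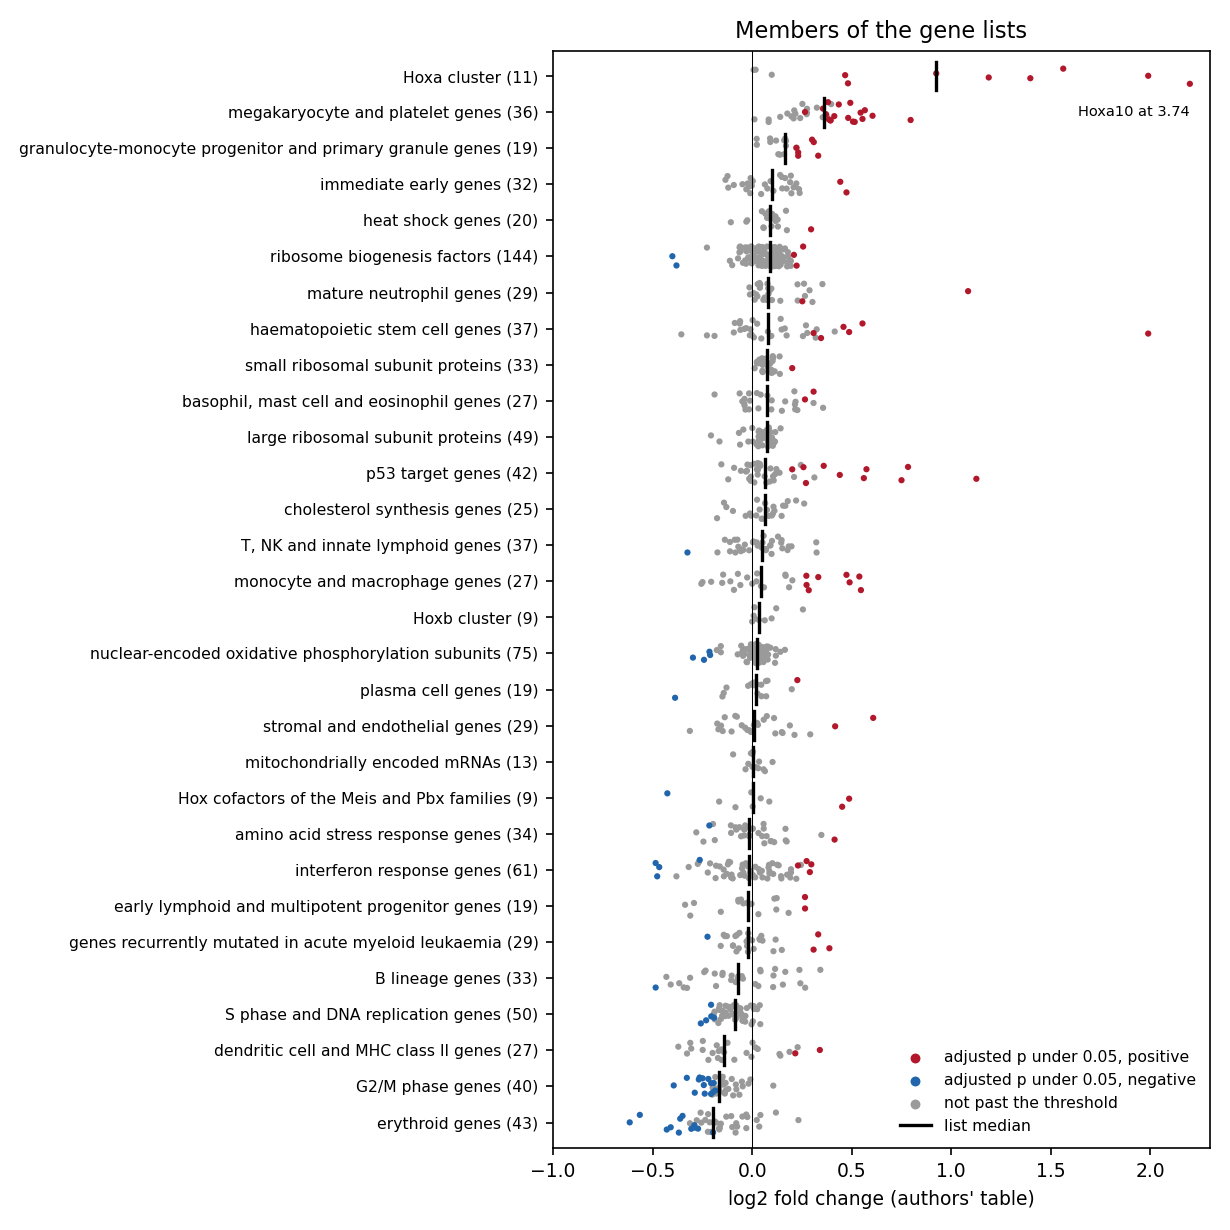
Each point is the log2 fold change of 1 list member in the authors' deposited table, coloured by whether its adjusted p was under 0.05, and black bars are list medians. The lists are ordered by median, from erythroid genes at -0.20 to the Hoxa cluster at 0.93, with the number of measured members in brackets and Hoxa10 (3.74) drawn at the right edge.

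Interferon response genes went both ways 6 weeks after pIpC. Of 61 members 4 were called positive and 4 negative in the authors' deposited table, and 7 and 8 when adjusted over the list alone. Psmb8 and Tgtp2 were higher at 0.29 (SE 0.07) and 0.30 (SE 0.08), and Oas3 and Samd9l lower at -0.48 (SE 0.09) and -0.47 (SE 0.10), in the authors' deposited table. The interferon list was not called (cameraPR adjusted p = 0.699, random lists 0.273). Immediate early genes had a median of 0.10 (random lists, adjusted p = 0.000689; cameraPR, adjusted p = 0.00275), with Klf4 and Fosl2 called at 0.47 (SE 0.09) and 0.44 (SE 0.09) among 32 members of the authors' deposited table, and 4 when adjusted over the list alone. Heat shock genes had a median of 0.09 (random lists, adjusted p = 0.00661; cameraPR, adjusted p = 0.000358), with 1 of 20 called in the authors' deposited table and when adjusted over the list alone, Hsph1 at 0.30 (SE 0.08). Of 34 genes of the amino acid stress response, Cebpb was higher at 0.41 (SE 0.11) and Pck2 lower at -0.21 (SE 0.07) in the authors' deposited table, 1 call per direction also when adjusted over the list alone, and the list was not called (cameraPR adjusted p = 0.92, random lists 0.42). None of 25 cholesterol synthesis genes was called by DESeq2 in the authors' deposited table or when adjusted over the list alone, 3 had an unadjusted p under 0.05, and the list was not called (cameraPR adjusted p = 0.145, random lists 0.175). The smallest p in that list belonged to Mvk and Srebf2, at 0.26 (SE 0.12) and -0.13 (SE 0.06) in the authors' deposited table.

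Among 29 genes that are recurrently mutated in acute myeloid leukaemia, 4 were called in the authors' deposited table and when adjusted over the list alone, and the list was not called (cameraPR adjusted p = 0.892, random lists 0.158). Idh1 and Cebpa were higher at 0.39 (SE 0.07) and 0.33 (SE 0.07) in the authors' deposited table, as was Gata2, and Rad21, of the cohesin ring, was lower at -0.22 (SE 0.06). Of 5 measured sex-linked check genes none was called by DESeq2 in the authors' deposited table, and Xist, with a mean of 33620 and a log2 fold change of -0.40 (SE 0.14, DESeq2 adjusted p = 0.0748), was the 1 called when adjusted over the list alone and the 1 with an unadjusted p under 0.05. The other members, Uty among them at -0.08 (SE 0.05), had means under 10 in the authors' deposited table, and the list was not called (cameraPR adjusted p = 0.188, random lists 1).

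Fisher's exact test on the called genes of the authors' deposited table found 9 lists over-represented. Positive calls were over-represented in the Hoxa (adjusted p = 6.47e-11), megakaryocyte (5.05e-20), p53 (7.66e-08), monocyte (3.3e-07), granulocyte-monocyte progenitor (1.04e-05) and stem cell (0.000579) lists. Negative calls were over-represented in the G2/M (1.54e-13), erythroid (1.52e-10) and S phase (0.0142) lists by Fisher's exact test, the last not against genes with a mean of at least 10 (0.0758). With 2 libraries per arm and no values per library here, no call could be tested by leaving a library out. The strand setting of the counting is not stated, so reads from antisense partners, such as Hoxaas3 beside Hoxa5, Hoxa6 and Hoxa7, cannot be told apart.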

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

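The centred fold changes, the removal of a GC and length trend, the lists without shared members and the set test on genes with a mean of at least 50 were chosen after the data were seen. Of the 919 calls, 557 were left at an adjusted p of 0.01 and 28 with a log2 fold change of at least 1, both by the stricter rule itself. The count was 1245 at 0.1, 808 without predicted genes, pseudogenes and segments, and 919 with a mean of at least 10 or a recomputed adjustment. Adjusted over the list alone, 25 G2/M, 12 granulocyte-monocyte progenitor and 10 stem cell genes were called in place of 14, 6 and 6. At 0.1, 9 ribosome biogenesis factors were called in place of 5. Of 84 named genes 73 were called, 61 at 0.01 and 76 at 0.1.

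The Hoxa, megakaryocyte, erythroid, G2/M, p53, ribosome biogenesis, S phase and granulocyte-monocyte progenitor lists kept their direction and their side of the threshold under every alternative of the random-list test and of cameraPR, the preset correlation of 0.05 included. The exceptions among the lists that lead the text were these. The stem cell list was lost without shared members (median 0.025, cameraPR adjusted p = 0.0941), which also left a smaller list. The monocyte list was lost in the rank-based set test (0.104) and was called against unmatched random lists (median 0.045). S phase genes were not over-represented against genes with a mean of at least 10 (0.0758). The cause of these changes was not tested. Some lists that were not called changed sign. Centred, the medians of the Meis and Pbx, mitochondrial and stromal lists were -0.0085, -0.0068 and -0.0025. With the GC and length trend removed, the Meis and Pbx and stromal medians were -0.0071 and -0.0024, and without shared members -0.00045 and -0.0057. In cameraPR the early lymphoid list turned negative with log2 fold changes (adjusted p = 0.774), ranks (0.918) and a mean of at least 50 (0.991), and the amino acid (0.923) and leukaemia lists (0.902) turned positive with log2 fold changes. With a preset correlation of 0.05, 2 other lists lost their call in cameraPR, large subunit proteins and basophil genes (both 0.0968). Over all alternatives the remaining lists lost 4 calls and gained 3 in the random-list test, and lost 4 and gained 5 in cameraPR. Of those gained in cameraPR, the Hoxb (0.0197), cholesterol (0.0223) and dendritic cell (0.0296) lists were called in the rank-based form. With log2 fold changes the dendritic cell (0.0142) and B lineage (0.0135) lists were called.

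Settings for values per sample were not run, because the table holds no columns of single samples, and for the same reason no library was left out. No paired analysis was possible because the labels give no groups. The shrunken fold changes limit what genes of low abundance can show.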

Other observations

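All tests of the Rpl30 base and of the region around Rpl30, and those of a lower erythroid share and of fewer dividing cells, were chosen after the result was seen, while the others were written down before their result. Every pattern was found and weighed in the same table.

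Replication-dependent histone genes, whose mRNAs accumulate in S phase and mostly lack a poly(A) tail, had a median log2 fold change of -0.05 over 40 members in the authors' deposited table, with 2 called, both negative. Immunoglobulin variable segments with a mean of at least 50 went both ways in the authors' deposited table, with 6 of 149 called positive and 7 called negative.

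Megakaryocyte genes were higher and erythroid genes lower in the positive arm. A lower erythroid share alone would raise the markers of all other cells alike, but the megakaryocyte median exceeded the B lineage median by 0.44 (permutation p = 1.0e-05, the smallest 100000 resamples can give). A trend of the fold change on GC content or transcript length is also argued against, since the gap between the megakaryocyte and erythroid medians was 0.56 before and 0.57 after its removal. Fewer dividing cells stay open for the erythroid part. The erythroid median differed from the G2/M median by -0.032 (permutation p = 0.214). The S phase median lay above the G2/M median by 0.08 (permutation p = 0.00068), so the genes of division did not fall alike. Neither difference can decide this, since fewer dividing cells need not lower these lists by the same amount. A shift of the progenitor mix towards megakaryocyte-biased cells and a change of these genes within cells also stay open and were not tested. The permutations swap members between lists as if genes were independent, so their p does not measure the spread between libraries.

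Copies of Rpl30 hold 6 of the positive calls, 3 of them (Gm12191, Rpl30-ps9 and Rpl30-ps10) with log2 fold changes of 2.36, 2.41 and 2.39 in the authors' deposited table, while Rpl30 itself (chromosome 15) was at -0.21. The called copies were 98.9% to 99.7% identical to the Rpl30 transcript, with a median of 99.1%, along the whole length of the copy, and the 5 other copies at most 97.7%. The copies cover 39.2% of the longest Rpl30 transcript, not the 90% that was asked for beforehand, so that test could not tell whether reads were shared. A constant share of Rpl30 reads would move the copies with Rpl30, at -0.21. The 6 called copies lay between 0.85 and 2.41, which argues against a constant share for them. A share that differs between the arms stays open. Pseudogenes of other ribosomal proteins (median 0.052 over 112) and the nearest neighbours of the called copies (0 of 12 called) argue against a change of counting at large or of transcription around each copy. All 11 copies differ from the 505-base Rpl30 transcript by G203A, counted from 1 at its 5′ end. With gaps and unaligned ends left out, G203A is the only substitution in Gm12191 and Rpl30-ps10. The latter was 99.1% identical to the longest Rpl30 transcript over 347 bases. The more 75-base placements across that base matched a copy with no other difference, the larger was its difference between the arms. That difference is in normalized counts, as mean and fold change imply. Over the 11 copies Spearman's rho was 0.93 (permutation p = 7.0e-05) and Pearson's r 0.90 (permutation p = 4.0e-05). Without Rpl30-ps9 and Rpl30-ps10, Pearson's r was 0.82. These 2 tie with Gm12191, which stayed in, as the copies farthest from the median number of placements. The called copies had 1 to 4 substitutions, while the 5 others had 5 to 20 and 0 such placements. The correlation therefore cannot tell that base from overall likeness to Rpl30. A base of Rpl30 that differs from the reference in 1 arm, such as a strain variant, could have sent Rpl30 reads to its copies. It stays open beside other ways in which the share of such reads could differ between the arms. Rpl30 itself was not called (adjusted p = 0.0526). Single copies gained at most 2874 normalized counts, while the estimate for Rpl30 fell by 3560, and the 9409 gained by the called copies in sum may hold the same read more than once, since how such reads were counted is not stated. With such a base, the fold changes of Rpl30 and its copies would not measure expression.

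Among genes with a mean of at least 50, called genes also lay beside one another in the genome somewhat more often than random placement gives. Outside the Hox genes 74 neighbouring pairs were both called, against a mean of 59.1 in random placements (one-sided permutation p = 0.0235). With overlapping genes left out there were 66 (mean 52.6, one-sided permutation p = 0.0281). Both counts lie above 95% of random placements, as set beforehand. They argue against random placement and against shared reads of overlapping genes alone. The placements scatter the calls as if genes were independent, so the counts do not tell why neighbours were called together. The margin is small, the second count lying on the upper bound of the central 95%, but the count was 1.25 times the random mean with and without the overlapping genes. Within 5 Mb of Rpl30, 6 of 36 genes were called (odds ratio 2.80, 95% confidence interval 0.949 to 6.85, Fisher's exact p = 0.0308), an interval that reaches below 1, and in a scan of the genome without the Hox genes no 10-Mb window passed Benjamini-Hochberg adjustment (smallest adjusted p = 0.806, and 0.932 for the window that holds Rpl30). Within 10 Mb of Npm1, 7 of 61 were called (odds ratio 1.81, 0.693 to 4.01, p = 0.127), too few to tell whether a segment linked to Npm1 differs. Whether segments from another strain differ between the arms, near Rpl30, near Npm1 or elsewhere, thus stays open.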
